A study of Homo sapiens with 10 samples.

How the data were processed

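Scalp samples of 5 patients were compared, 1 affected and 1 control sample per patient. Group and patient were taken from the sample labels, which pair the samples because both come from the same person. Per the labels' protocols the tissue was kept in a stabilising reagent and frozen, total RNA was extracted with a kit for fibrous tissue, and it was labelled with biotin by a whole-transcript kit. The submitters' processing notes name RMA and Partek without versions, and the genome build and the version of the probe set annotation are not given in the sources used here. RMA corrects background, aligns the distributions of the arrays and summarises the probes of a set. Such alignment removes any change shared by all genes, so differences are relative to the array as a whole.

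The deposited values are on the log2 scale, 1 per probe set and array, and were used as deposited. They ranged from 2.06 to 13.58, with array medians from 6.11 to 6.16, which is the range RMA values take. No array column was identical to another, and arrays correlated between 0.978 and 0.988. No count or depth exists for arrays, and no detection call was used here, so dim probe sets were marked instead. A probe set was called dim when its mean lay under the 25th percentile of all means, 4.51. Of 21448 probe sets 17709 had 1 gene symbol in the annotation given, 0 had several and 3739 were unnamed here. All 17709 symbols matched by gene identifier to the reference gene table, and 0 were updated. XIST, TSIX and Y-linked genes were left out of all steps, and 21371 probe sets were tested, 17682 of them named. For gene lists 1 probe set stood for a gene, the one with the highest mean, and 17 genes had more than 1. No genome coordinates were used.

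Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with the patient as a fixed block, which leaves 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all probe sets tested, with a threshold of 0.05. Errors given with genes are limma's moderated standard errors, and errors given with lists are SDs of the list's mean difference over 5 pairs. The pairing was checked by the correlation of deviations from the group means. It was 0.147 to 0.332 within pairs and −0.203 to 0.0981 across pairs, and all 5 affected samples matched their own pair best.

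Gene lists for cell types, pathways and tissue handling were written before the data were examined, 41 lists with 887 genes, of which 805 had a named probe. Of these genes 14 stand in more than 1 list. The lists were tested with camera at a preset inter-gene correlation of 0.01, which assumes that genes of a list vary almost independently between samples, and adjusted over the 41 lists. Alternatives were camera with the correlation estimated per list, fry, and an exact exchange of samples within pairs. Camera compares a list with all other genes, whereas fry tests whether its genes move one way on balance and, in its mixed form, whether they change in either direction. Member genes were also adjusted over the list alone.

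Apart from the exceptions given below, the genes named in the text follow a rule set before the data were examined. Its first part takes the 12 largest positive and 12 largest negative differences past the threshold that moved one way in all 5 pairs. Where fewer pass, it turns to genes that moved that way in all 5 pairs with a mean difference of at least 0.5 log2. Of these it takes the ones with the smallest unadjusted p. Symbols of uncharacterised loci, small RNAs, open reading frames and immunoglobulin or T cell receptor segments were skipped. The second part takes up to 4 members of each list with the smallest unadjusted p. The text names only some of these, and the rule does not fix which. The third part always names COL1A1, COL1A2, COL3A1, PDGFA, PDGFB, PDGFRB, TGFB1, ACTA2, POSTN, FAP, MMP1, MMP2, MMP7, MMP9, PPARG and KRT15 where measured. Outside the rule, SFRP4, FN1, SPARC, COL5A2 and KRT79 are named because they passed the threshold over their list alone. Some keratin-associated proteins, and genes under other observations, also stand outside it.

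The fit was tested on simulated data with the real probe sets' means and spread. Of 100 probe sets changed by log2 1, 76 were recovered, of 100 changed by log2 2, 98 were recovered, and 7 unchanged ones were called. The changed probe sets were drawn at random, and the median standard error was 0.117. Genes with large real differences had larger errors, such as 0.22 for ADAM12 and 0.44 for KRTAP1-1, so these shares do not hold for them. A list shifted by 0.3 log2 was recovered with 0 other lists called. The simulated noise was independent between genes, whereas the estimated correlation was 0.27 for the fibroblast activation list. The simulation therefore does not show how often lists are falsely called when their genes vary together. Alternatives were no patient block, a random patient block, a second quantile normalization, median centring, filters on dim probe sets, an intensity trend or robust prior in eBayes, array weights, other thresholds, and leaving out each pair. A preset correlation of 0.05, the exact exchange, leaving out each pair with the estimated correlation, and the unadjusted threshold were added after the data were seen. Figures were drawn with matplotlib 3.10.9.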

Results

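Central centrifugal cicatricial alopecia is a scarring hair loss that starts at the crown of the scalp and spreads outwards, with loss of hair follicles and fibrosis around them. Total RNA from scalp of 5 patients was hybridised to 1-colour expression arrays, with 1 affected and 1 control sample per patient, which makes 10 arrays and 5 pairs. The arrays held 21448 probe sets, of which 21371 were tested, and 17663 genes had a named probe. Array medians lay between 6.11 and 6.16 on the log2 scale, and RMA, which aligns the arrays, fixes this likeness. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.117. The comparison asked which genes, and in particular which markers of activated fibroblasts, differed between affected and unaffected scalp of the same patients.

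In affected scalp the fibroblast activation list rose and the sebaceous gland list fell by camera with a preset correlation, and neither passed with an estimated correlation. The fibroblast activation list averaged 0.34 ± 0.27 log2 higher in affected scalp (SD, n = 5 pairs), and the sebaceous gland list averaged −0.43 ± 0.60. Of 41 gene lists fixed before the data were examined, 27 passed an adjusted p of 0.05 by camera with a preset correlation of 0.01, 18 of them higher and 9 lower. With a correlation estimated from the data 0 lists passed, and the smallest adjusted p was 0.245 with an estimated correlation. Fry, testing whether a list moves 1 way on balance, and exact exchange of samples within pairs also called 0 lists, and 5 pairs allow a smallest exact two-sided p of 0.0625. Mixed fry, which tests for change in either direction, called 5 lists. These were complement, outer root sheath and bulge, mast cells, growth factors of fibrosis, and basal keratinocytes and basement membrane, at adjusted p from 0.0013 to 0.031. At an unadjusted p under 0.05, 5 lists passed with an estimated correlation. These were complement, mast cells, macrophages and monocytes, outer root sheath and bulge, and dermal matrix.

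At the level of single genes, limma called 0 genes at an adjusted p of 0.05, and the smallest adjusted p was 0.452. At an unadjusted p under 0.05 there were 1266 probe sets, 608 higher and 658 lower, against 1069 expected by chance. With an intensity trend in the variance prior, 2 genes passed, TMPRSS11E and PLIN2, both lower in affected scalp. All 5 pairs moved up for 751 probe sets and down for 720, together 6.88%, where chance gives 6.25%. A log2 difference of at least 1 in size was reached by 37 probe sets, 9 higher and 28 lower, and 22 of the lower ones were keratin-associated proteins.

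The genes named next moved one way in all 5 pairs and had a mean difference of at least 0.5 log2 in size. Among such genes they had the smallest unadjusted p, and none passed the threshold over all genes. Single pairs could lie nearer 0, such as C1QTNF6 at 0.03 and MMP2 at 0.12 in pair 1. Higher in affected scalp was ADAM12, a metalloproteinase of activated mesenchymal cells, at 1.18 ± 0.22 log2 (SE, n = 5 pairs). SFRP2, a secreted modulator of Wnt signalling, differed by 0.87 ± 0.15 and GPR15LG, a ligand of a T cell homing receptor, by 0.87 ± 0.16. The secreted protease ADAMTS12 differed by 0.79 ± 0.13, the neurotrophin receptor NTRK3 by 0.78 ± 0.12 and C1QTNF6 by 0.74 ± 0.15. MMP2, a gelatinase, differed by 0.68 ± 0.14, and the transcription factor ZIC1 by 0.66 ± 0.11. The sulfotransferase SULT1A1 differed by 0.58 ± 0.09 and PDGFRB, the receptor of platelet-derived growth factor on mesenchymal cells, by 0.55 ± 0.10. PACC1 differed by 0.53 ± 0.11, at a signal in the dimmest 25% of probe sets, and CDHR1 by 0.50 ± 0.10.

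Lower in affected scalp was RARRES1, a retinoid-responsive gene, at −0.97 ± 0.16 log2 (SE, n = 5 pairs). GLDC, of the glycine cleavage system, differed by −0.89 ± 0.17, and ANGPTL7 by −0.75 ± 0.12. TMPRSS11E, a serine protease of epithelia, had the smallest unadjusted p of all genes and differed by −0.72 ± 0.09. B4GALNT2 differed by −0.71 ± 0.15, and the lipid droplet protein PLIN2 by −0.70 ± 0.10. PNLDC1 and the hair keratin KRT84 both differed by −0.68, with standard errors of 0.13 and 0.10, and the affected mean of PNLDC1, 4.34, lay under 4.51, the limit for dim probe sets (the dimmest 25%). EVA1A, in the dimmest 25% of probe sets, differed by −0.60 ± 0.11, and IFT80, of the cilium, by −0.58 ± 0.11. The epidermal lipase LIPK differed by −0.52 ± 0.11 and SC5D, an enzyme of cholesterol synthesis, by −0.51 ± 0.10.

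**Figure D1:**
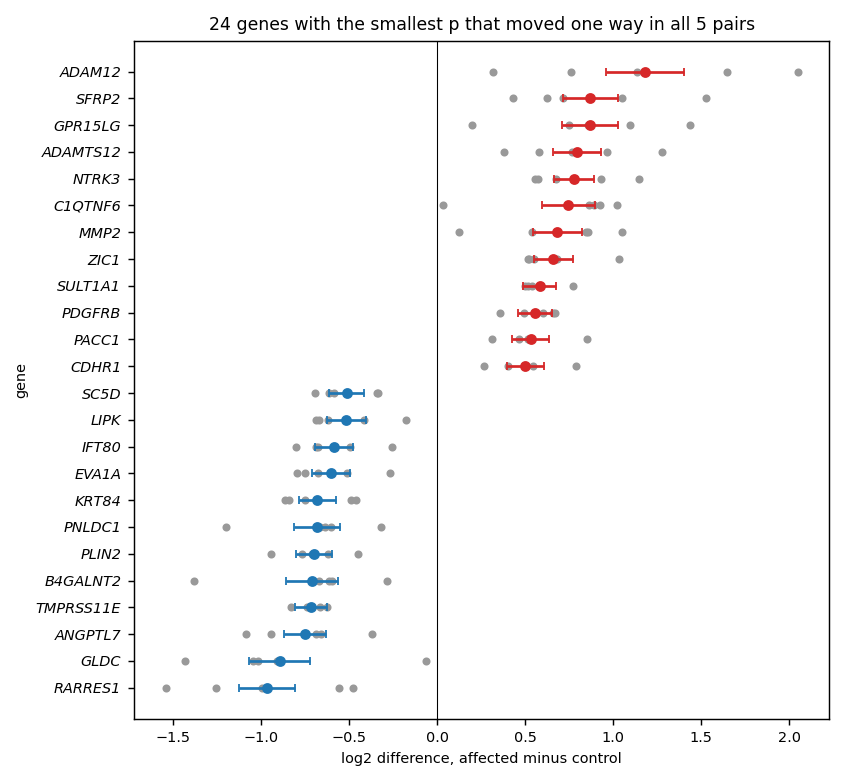
Log2 difference (affected minus control, x axis) for 24 genes with the smallest unadjusted p that moved one way in all 5 pairs. Grey points are pairs, and coloured points with bars are the mean and its limma standard error, from 1.18 for ADAM12 to −0.97 for RARRES1.

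Fibroblast and matrix genes formed the group that the comparison asked about in particular. The fibroblast activation list rose by 0.34 ± 0.27 log2 (SD, n = 5 pairs) and was higher in 4 of 5 pairs (camera adjusted p = 3.3e-11, and adjusted p = 0.343 with an estimated correlation). The list was at 0.47, 0.42 and 0.65 in pairs 2, 3 and 5, the pairs in which the immediate early list, a sign of tissue handling, was at −0.33, −0.20 and −0.35. In pairs 1 and 4 it was at −0.05 and 0.22, and the immediate early list at −0.01 and 0.10. Of the 32 measured members of the fibroblast activation list 25 had a mean difference above 0. Adjusted over the list alone 11 rose, 0 fell and 21 did not pass, while over all genes 0 passed. The 11 were ADAM12, COL6A3, COL5A1, THY1, SFRP4, FN1, LOX, SPARC, COL1A1, COL1A2 and COL5A2. FN1, which encodes fibronectin, differed by 0.97 ± 0.25 (SE) and COL6A3 by 0.81 ± 0.19. COL1A1 and COL1A2, the chains of type I collagen, differed by 0.71 ± 0.21 and 0.55 ± 0.17, both higher in 4 of 5 pairs. This list and the growth factor and metalloproteinase lists hold genes known to have been examined by the study on these samples. The means, tests, pair counts and member counts of these lists are therefore not independent evidence of direction.

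The dermal matrix list rose by 0.24 ± 0.17 log2 (SD, n = 5 pairs) and was higher in 5 of 5 pairs (adjusted p = 3.4e-09, and adjusted p = 0.343 with an estimated correlation). It was at 0.41, 0.26 and 0.39 in pairs 2, 3 and 5, in which the immediate early list was lowest, and at 0.03 and 0.10 in pairs 1 and 4. Of 24 members 3 rose, adjusted over the list alone, against 0 over all genes. They were COL6A2 at 0.53 ± 0.11 (SE), the hyaluronan synthase HAS2 at 0.52 ± 0.13 and COL6A1 at 0.62 ± 0.16. The list of metalloproteinases and their inhibitors rose by 0.34 ± 0.41 log2 (adjusted p = 4.1e-05, and adjusted p = 0.370 with an estimated correlation), and it averaged 0.18 without pair 5. It was at 0.38, 0.27 and 1.00 in pairs 2, 3 and 5, again those with the lowest immediate early list, and at −0.09 and 0.15 in pairs 1 and 4. Of its 17 members MMP2 rose, adjusted over the list alone, and 0 passed over all genes. The collagenase MMP13 differed by 1.49 ± 0.57, or 0.97 without pair 5 and 2.24 without pair 1, with a control mean of 3.94, under the dim limit of 4.51. MMP1 differed by 1.10 ± 0.62 and was higher in 3 of 5 pairs, and without pair 5 its difference was 0.21. MMP9 differed by 0.63 ± 0.35, or 0.23 without pair 5 and 0.98 without pair 4, and MMP7 by 0.33 ± 0.15, or 0.51 without pair 1.

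Growth factors of fibrosis rose by 0.07 ± 0.12 log2 (SD, n = 5 pairs) and were higher in 3 of 5 pairs (adjusted p = 0.0419, and adjusted p = 0.510 with an estimated correlation). These were pairs 2, 3 and 5, at 0.20, 0.18 and 0.05, in which the immediate early list was lowest, and pairs 1 and 4 were at −0.02 and −0.08. The call was lost without pair 2, 3 or 5, at means of 0.03, 0.04 and 0.07, and the mean was 0.11 without pair 4. Adjusted over the list alone 3 of 30 members rose, against 0 over all genes. They were the receptors PDGFRB and PDGFRA, at 0.55 ± 0.10 (SE) and 0.37 ± 0.10, and INHBA, a subunit of activin, at 0.51 ± 0.12, each higher in 5 of 5 pairs. TGFB1 differed by 0.30 ± 0.11 and was higher in 4 of 5 pairs. The ligands PDGFA and PDGFB differed by −0.11 ± 0.13 and −0.03 ± 0.14, and each turned direction without pair 5, to 0.03 and 0.01. PDGFB was also at 0.08 without pair 3 and −0.15 without pair 4, and PDGFA at −0.18 without pair 3 or 4. The serine protease FAP differed by 0.65 ± 0.27, or 0.32 without pair 5, and periostin, POSTN, by 0.43 ± 0.20, or 0.68 without pair 1. Smooth muscle actin, ACTA2, differed by 0.14 ± 0.13, or 0.05 without pair 2 and 0.26 without pair 5. PPARG, a regulator of lipid metabolism, differed by −0.04 ± 0.20, and by 0.20 without pair 4 and −0.20 without pair 3. COL3A1 and KRT15 had no named probe here.

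**Figure D2:**
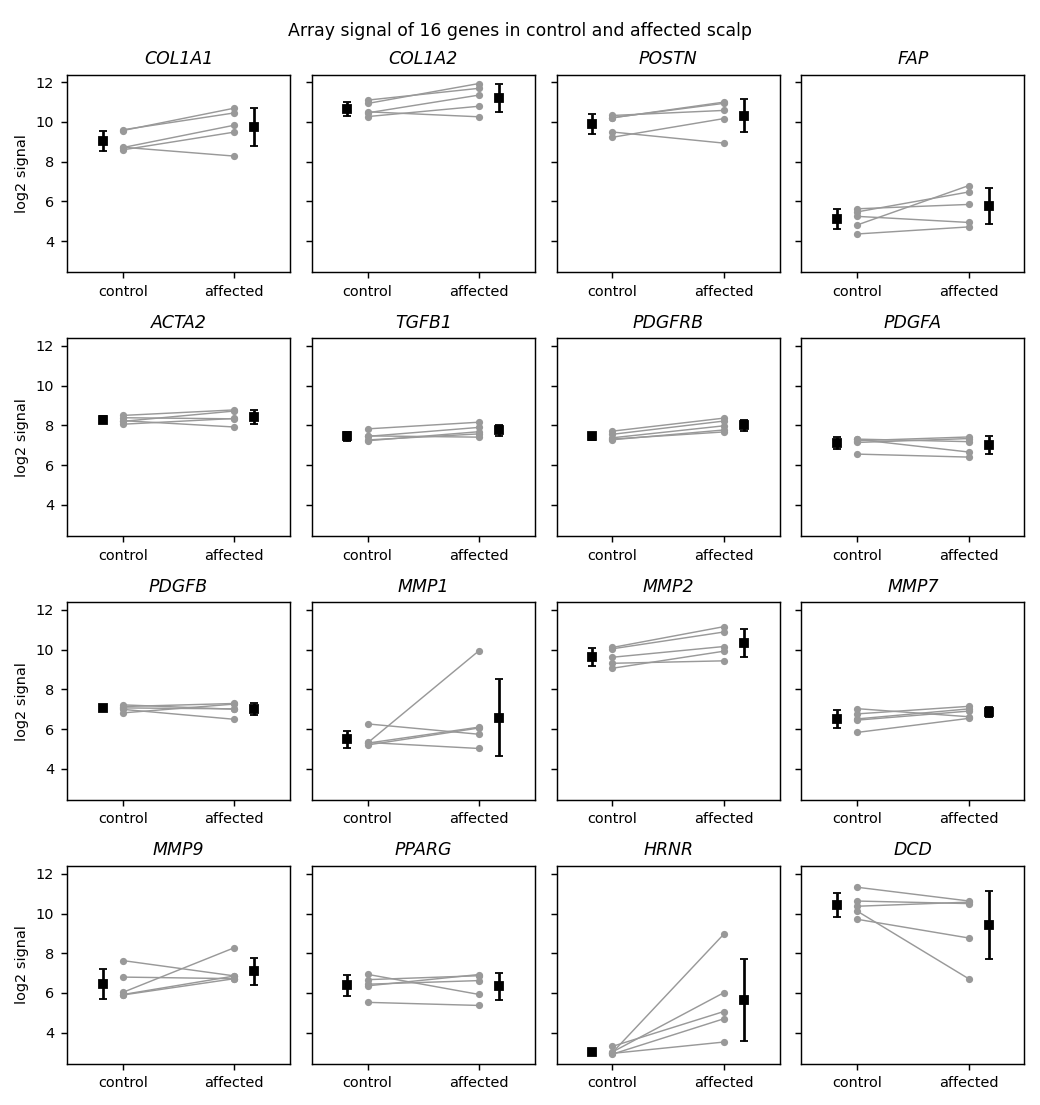
Log2 array signal (y axis) of 16 genes in control and affected scalp. Grey lines join the samples of 1 pair, and black squares with bars are means ± SD over 5 samples. The differences ranged from 2.61 for HRNR to −0.99 for DCD, and pair 5 held the extreme affected sample of both.

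Lists of sebaceous and lipid genes were tested next. The sebaceous gland and sebum lipid list fell by 0.43 log2, with an SD of 0.60 over 5 pairs, and was lower in 4 of 5 pairs (adjusted p = 3.3e-11, and adjusted p = 0.413 with an estimated correlation). Its mean was −0.68 without pair 5. Of its 34 members 33 had a mean difference below 0, and 5 fell, adjusted over the list alone, against 0 over all genes. These were PLIN2, the sterol acyltransferase SOAT1 at −0.85 ± 0.18 (SE), FA2H at −0.67 ± 0.16, ACSBG1 at −0.71 ± 0.20 and the sebaceous keratin KRT79 at −0.88 ± 0.26. Cholesterol synthesis genes fell by 0.11 log2 (SD 0.14, adjusted p = 0.0091, and adjusted p = 0.488 with an estimated correlation). That call was lost without pair 3 or 4, at −0.09 and −0.08. SC5D alone among 19 members fell, adjusted over the list alone. Peroxisome and fatty acid oxidation genes fell by 0.12 log2 (SD 0.13, adjusted p = 0.00308, and adjusted p = 0.469 with an estimated correlation), and the call was lost without pair 4, at −0.08. ACADM and ACAA2, enzymes of fatty acid oxidation, differed by −0.60 ± 0.16 and −0.52 ± 0.15, and 0 of 24 members passed over the list alone.

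Hair follicle lists moved by different amounts. Keratin-associated proteins, the matrix of the hair fibre, fell by 0.65 log2, with an SD of 1.14 over 5 pairs (adjusted p = 1.7e-09, and adjusted p = 0.488 with an estimated correlation). They were lower in 3 of 5 pairs, and the mean was −0.32 without pair 1, −0.42 without pair 3 and −0.99 without pair 2. KRTAP1-1, KRTAP1-5 and KRTAP3-2 differed by −1.25 ± 0.44, −1.26 ± 0.46 and −1.18 ± 0.42 (SE), and KRTAP1-5 was at −0.84 without pair 1. Among the list 0 of 28 members passed over the list alone or over all genes. Members of the same subfamily can be near-identical copies, and a probe can read several of them. The 15 members with an unadjusted p under 0.05 were all lower and all of the KRTAP1, KRTAP2, KRTAP3, KRTAP4 and KRTAP9 subfamilies. Outside these, values lay on both sides of 0, such as KRTAP5-1 at −0.35 ± 0.18 and KRTAP8-1 at 0.77 ± 0.89. In the whole list 24 members had a mean difference below 0 and 4 above. Hair shaft keratins fell by 0.19 log2 (SD 0.71, adjusted p = 0.0395, and adjusted p = 0.675 with an estimated correlation). The call was lost without pair 1 or 3, at −0.10 and −0.12, and without pair 4 the mean was 0.01. It was −0.37 without pair 2 and −0.39 without pair 5. KRT84, adjusted over the list alone, was the single member of 13 that fell. KRT37 differed by 0.49 ± 0.19 and was higher in 4 of 5 pairs. The members with the highest signal, KRT31 and KRT85, differed by −0.15 ± 0.24 and 0.04 ± 0.31. Of the 13 members 9 had a mean difference below 0 and 4 above.

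The inner root sheath list fell by 0.18 log2 (SD 0.40, n = 5 pairs, adjusted p = 0.0042, and adjusted p = 0.510 with an estimated correlation). It was −0.02 and not called without pair 4, and −0.28 without pair 5. LIPH, a lipase needed for hair growth, differed by −0.39 ± 0.11 (SE), and 0 of 21 members passed over the list alone. Outer root sheath and bulge genes fell by 0.15 log2 (SD 0.08, adjusted p = 2.6e-04, and adjusted p = 0.245 with an estimated correlation) and were lower in 5 of 5 pairs. ANGPTL7 at −0.75 ± 0.12, the stem cell receptor LGR5 at −0.44 ± 0.11 and the transcription factor SOX9 at −0.35 ± 0.10 fell, adjusted over the list alone, and 0 of 20 members passed over all genes. Of the 20 members 13 had a mean difference below 0 and 7 above. The hair matrix and hair cycle list averaged −0.07 ± 0.21 and was not called (adjusted p = 0.133). It was called without pair 3 or 5, at −0.10 and −0.13, and lay at 0.0023 without pair 4. The dermal papilla and dermal sheath list averaged 0.09 ± 0.19 and was not called (adjusted p = 0.123), but was called without pair 1, at 0.16, and lay at 0.03 without pair 3. Within it SFRP2 and INHBA rose, adjusted over the list alone, and 0 of 18 members passed over all genes.

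In the epidermis, the differentiation list rose by 0.30 ± 0.29 log2 (SD, n = 5 pairs) and was higher in 5 of 5 pairs (adjusted p = 3.4e-09, and adjusted p = 0.413 with an estimated correlation). The mean was 0.18 without pair 5. All 28 members had a mean difference above 0, and 0 passed over the list alone. HRNR, hornerin of the cornified layer, had the largest log2 difference of all probe sets, 2.61 ± 0.62 (SE), and was higher in 5 of 5 pairs. Its control samples averaged 3.05, in the dimmest 25% of probe sets, and its affected samples 5.66 with an SD of 2.05. Without pair 5 the difference was 1.77. HRNR weighs on the mean of the differentiation list, whose median member was at 0.19. In pair 3 that list was at 0.02, while HRNR was at 2.92 in control and 4.70 in affected scalp. The list's rise in pair 3, and so its count of 5 of 5 pairs, thus rests on HRNR. The list of stressed keratinocytes rose by 0.26 ± 0.51 (adjusted p = 0.0042, and adjusted p = 0.607 with an estimated correlation). It was 0.14 without pair 4 and 0.12 without pair 5, where the call was lost, and 0.40 without pair 3. The defensin DEFB4A differed by 1.47 ± 0.46, or 0.90 without pair 5, with a control mean of 4.29, under the dim limit of 4.51, and has a near-identical copy. PI3, which encodes elafin, differed by 0.67 ± 0.19, and 0 of 18 members passed over the list alone. The basal keratinocyte and basement membrane list rose by 0.13 ± 0.09 (adjusted p = 0.0395, and adjusted p = 0.488 with an estimated correlation). Its call was lost without pair 2, 3, 4 or 5, at 0.13, 0.12, 0.12 and 0.10. COL4A1 and NID2, of the basement membrane, rose, adjusted over the list alone, by 0.54 ± 0.12 and 0.56 ± 0.14.

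Among immune cells the macrophage and monocyte list rose by 0.22 ± 0.22 log2 (SD, n = 5 pairs) and was higher in 5 of 5 pairs (adjusted p = 1.6e-08, and adjusted p = 0.245 with an estimated correlation). Without pair 5 the mean was 0.13. FCER1G differed by 0.49 ± 0.12 (SE) and C1QC by 0.30 ± 0.11, and 24 of 26 members had a mean difference above 0. Complement genes rose by 0.19 ± 0.07 in 5 of 5 pairs (adjusted p = 1.5e-05, and adjusted p = 0.245 with an estimated correlation), with C1S at 0.40 ± 0.11 and C7 at 0.57 ± 0.20. Mast cell genes rose by 0.18 ± 0.09 in 5 of 5 pairs (adjusted p = 2.1e-05, and adjusted p = 0.245 with an estimated correlation). Of 14 members the mast cell protease CPA3, at 0.40 ± 0.10, rose, adjusted over the list alone. B and plasma cell genes rose by 0.12 ± 0.08 in 5 of 5 pairs (adjusted p = 0.0302, and adjusted p = 0.343 with an estimated correlation), a call lost without pair 3, at 0.10. JCHAIN, of secreted antibodies, differed by 0.87 ± 0.26, or 0.54 without pair 4, with a control mean of 4.48, under the dim limit of 4.51. FCRL1, of the same list, differed by −0.28 ± 0.11 and was lower in 4 of 5 pairs. Of the 17 members of that list 12 had a mean difference above 0 and 5 below. In the macrophage, complement and B cell lists 0 members passed over the list alone.

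T cell genes rose by 0.12 ± 0.27 log2 (SD, n = 5 pairs, adjusted p = 0.0311, and adjusted p = 0.607 with an estimated correlation). The call was lost without pair 2, 4 or 5, at 0.12, 0.05 and 0.06, and the mean was 0.20 without pair 3. CD4 differed by 0.29 ± 0.11 (SE). Chemokine and lymphoid aggregate genes rose by 0.11 ± 0.22 (adjusted p = 0.0454, and adjusted p = 0.544 with an estimated correlation). That call was lost without pair 3, 4 or 5, at 0.11, 0.09 and 0.04, and the mean was 0.19 without pair 1. Without the dimmest 50% of probe sets it was −0.02. CXCL13, a B cell chemokine, differed by 1.12 ± 0.58, or 0.31 without pair 5, with a control mean of 3.97, under the dim limit of 4.51, and CCL22 by 0.24 ± 0.09. The class II antigen presentation list rose by 0.09 ± 0.20 (adjusted p = 0.0454, and adjusted p = 0.488 with an estimated correlation), lost without pair 3, 4 or 5, at 0.08, 0.02 and 0.08, and at 0.16 without pair 1. Neutrophil genes rose by 0.14 ± 0.28 (adjusted p = 0.0458, and adjusted p = 0.488 with an estimated correlation), lost without pair 4 or 5, at 0.07 and 0.06, and at 0.22 without pair 3. The interferon response list averaged 0.04 ± 0.32 and was not called (adjusted p = 0.241), but was called without pair 1 or 2, at 0.09 and 0.14. Without pair 4 or 5 it was −0.04.

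The cytotoxic lymphocyte list averaged 0.05 ± 0.16 log2 (SD, n = 5 pairs) and was not called (adjusted p = 0.437), with a median member of −0.003. Its mean ranged from 0.0021 without pair 4 to 0.10 without pair 1. Dendritic and Langerhans cell genes were not called (adjusted p = 0.846), with a mean just below 0, a median member of −0.05 and an upward direction in the test. Without pair 1 that list was called, at 0.11. In the T cell, chemokine, antigen presentation, neutrophil, interferon, cytotoxic lymphocyte and dendritic cell lists 0 members passed over the list alone.

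Further lists covered vessels, fat, sweat glands, hypoxia and tissue handling. Blood endothelium rose by 0.10 ± 0.14 log2 (SD, n = 5 pairs, adjusted p = 0.0115, and adjusted p = 0.488 with an estimated correlation), a call lost without pair 1 or 4, both at 0.07. KDR, a receptor of endothelial growth factor, differed by 0.43 ± 0.12 (SE). Adipocyte genes rose by 0.11 ± 0.47 (adjusted p = 0.0336, and adjusted p = 0.675 with an estimated correlation), lost without pair 1, 2 or 3, at 0.02, 0.03 and 0.08, and at 0.31 without pair 4. Hypoxia and glycolysis genes rose by 0.08 ± 0.09 (adjusted p = 0.0357, and adjusted p = 0.488 with an estimated correlation), lost without pair 3, 4 or 5, at 0.06, 0.05 and 0.07. Eccrine and apocrine gland genes fell by 0.18 log2 (SD 0.47, adjusted p = 0.0282, and adjusted p = 0.607 with an estimated correlation). Without pair 5 the mean was 0.02 and the call was lost, and without pair 2 it was −0.30. The sweat peptide DCD differed by −0.99 ± 0.43, or −0.39 without pair 5. LTF, lactoferrin, differed by 1.13 ± 0.37 and was higher in 3 of 5 pairs, at 0.76 without pair 3 and 1.45 without pair 5. Immediate early genes, which respond to tissue handling, fell by 0.16 log2 (SD 0.20, adjusted p = 0.00308, and adjusted p = 0.488 with an estimated correlation). DUSP1 differed by −0.54 ± 0.15 and EGR1 by −0.40 ± 0.13. In all 5 of these lists 0 members passed over the list alone.

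The remaining lists were not called, and 0 of their members passed over the list alone. Lymphatic endothelium averaged −0.08 ± 0.14 log2 (SD, n = 5 pairs, adjusted p = 0.458), or −0.05 without pair 1 and −0.04 without pair 2. Melanocytes averaged −0.02 ± 0.12 (adjusted p = 0.773), or 0.02 without pair 5 and −0.05 without pair 2. Pericytes and smooth muscle averaged 0.03 ± 0.24 (adjusted p = 0.832) and were called without pair 5, at 0.12, but lay at −0.02 without pair 2 and −0.03 without pair 3. Skeletal muscle averaged 0.01 ± 0.06 (adjusted p = 0.796) and housekeeping genes 0.004 ± 0.06 (adjusted p = 0.846). Skeletal muscle was just below 0 without pair 4 or 5, and housekeeping genes were at −0.02 without pair 2. Nerve and Schwann cells averaged 0.04 ± 0.07 (adjusted p = 0.796), with a median member of −0.02, and ranged from 0.02 without pair 3 to 0.07 without pair 5. Proliferation averaged −0.06 ± 0.21 (adjusted p = 0.117) and was called without pair 3 or 5, at −0.12 and −0.09, and lay at 0.02 without pair 4. Mitochondrial respiration averaged −0.06 ± 0.13 (adjusted p = 0.185) and was called without pair 1, at −0.11, but lay at −0.02 without pair 5. Red blood cell genes averaged −0.08 ± 1.35 (adjusted p = 0.995), with a median member of 0.03 and an upward direction in the test. That list was called without pair 3, at 0.41, and without pair 5, at −0.48, and lay at 0.05 without pair 2.

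**Figure D3:**
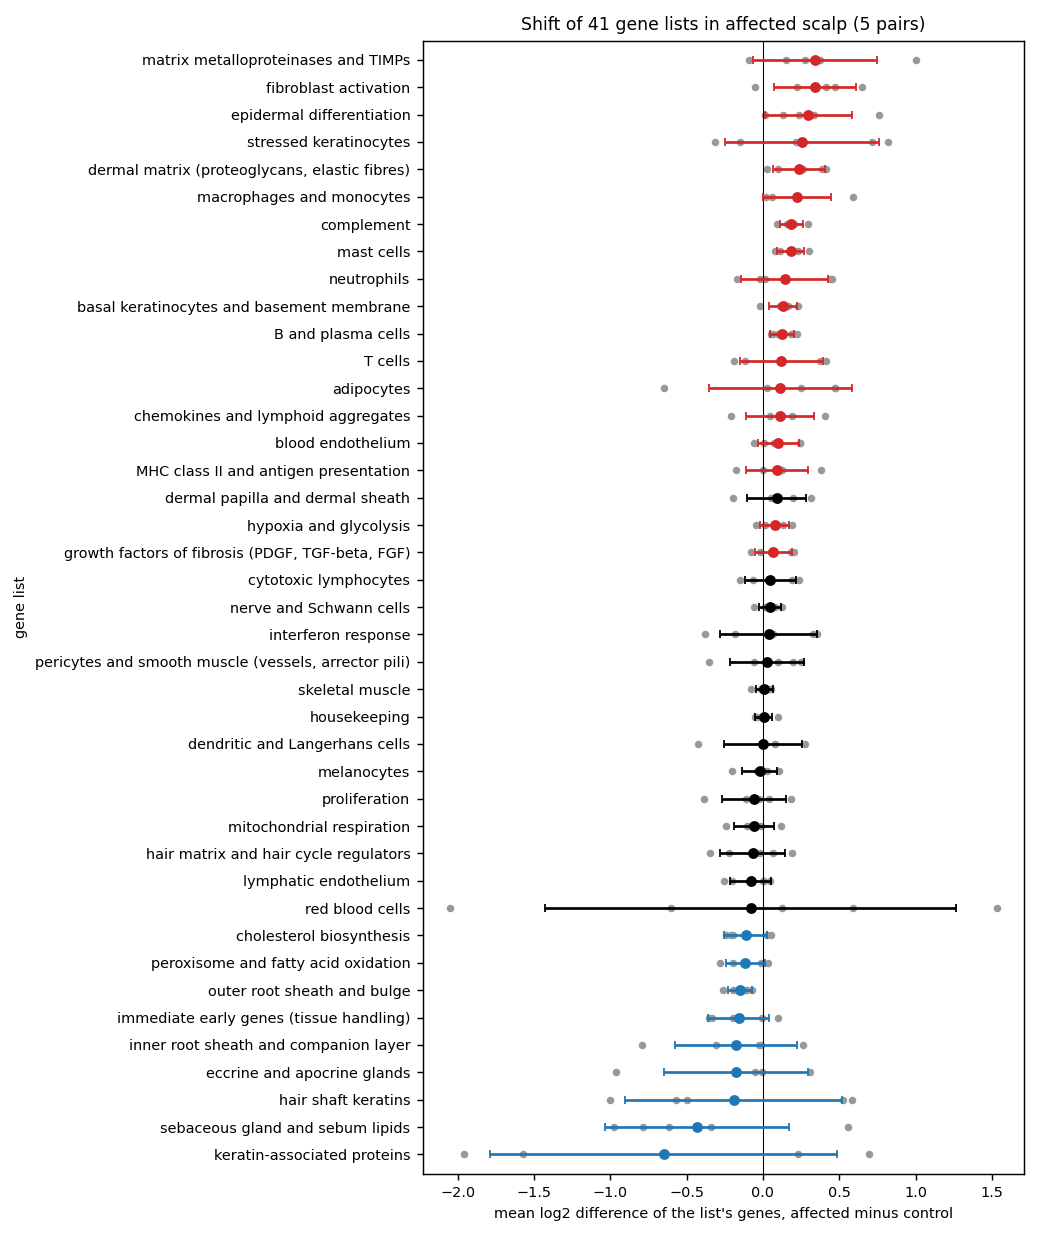
Mean log2 difference (affected minus control, x axis) of 41 gene lists. Grey points are the 5 pairs, and larger points with bars are the mean ± SD over pairs, in red for the 18 lists called higher, blue for the 9 called lower and black for the 14 not called by camera with the preset correlation. With an estimated correlation 0 lists were called.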

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

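Apart from the splits of the 10 samples for gene lists, the tests in this part were chosen after the results were seen. Among 154 groups of 5 samples, 11 held 1 sample whose gap to the nearest other exceeded the Dixon limit as a share of the group's range, and chance gives 7.7.

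Among lists, 1 sample stood apart in epidermal differentiation in affected scalp (gap 0.729 of the range), blood endothelium in affected scalp (0.742), nerve and Schwann cells in affected scalp (0.756) and skeletal muscle in control scalp (0.819). Among genes it did so for ZIC1 in control scalp (0.768), B4GALNT2 in affected scalp (0.727), LIPK in control scalp (0.747) and PDGFA in control scalp (0.776). MMP9 in affected scalp had a gap of 0.908, and MMP1 had 0.782 in affected and 0.883 in control scalp.

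Camera with the preset correlation called 27 of 41 lists. Of 100 splits of the 10 samples into 5 and 5, 3 called as many, the real one included, and the highest other called 30. That meets the bound set beforehand, but 87 of the 99 other splits put both samples of at least 1 pair into 1 group, where the patient block takes the pair out of the comparison, so chance cannot be excluded from them. Some splits also gave the same comparison again, the one that called 30 lists among them, so shares of the 100 splits here and below count repeats. The 16 exchanges within pairs are too few for a share under 0.05, with 27 for the real assignment, the 1 that called as many, and 24 for the highest other. The median of the other splits was 14 lists, so shared variation of genes within a list may account for many of the calls. With an estimated correlation 0 of the 27 calls were kept, but that loss cannot be put down to shared variation alone. The estimate was 0.27 for fibroblast activation, but −0.017 for complement and −0.012 for B and plasma cells. Still, camera's unadjusted p went from 2.6e-06 to 0.0070 for complement and from 0.013 to 0.056 for B and plasma cells.

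For the count of 0 genes past the threshold by limma, 100 of 100 splits gave as many, as any split must, so this says nothing about chance. At an unadjusted p under 0.05 there were 1266, and 26 of 100 splits gave as many, up to 1915.

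The fibroblast activation list was higher in affected scalp by 0.34 log2. It does not rest on 1 pair alone under the preset correlation, since without pair 5, which had the largest difference, its mean was 0.26 with a camera adjusted p of 4.4e-07, although 0 lists were called with an estimated correlation whichever pair was left out. A lower share of sebaceous and follicular tissue, which would raise every other tissue alike, may also raise it, but in pair 5 the sebaceous list was higher by 0.56 and the fibroblast list by 0.65, and in pair 1 they were at −0.78 and −0.05. The fibroblast list's mean minus that of the endothelial, smooth muscle and nerve lists was 0.283 (SE 0.156), within 2 SE of 0. Minus that of 6 lists of other tissues it was 0.327 (SE 0.134), beyond 2 SE, and each was above 0 in 4 of 5 pairs. With 5 pairs, 2 SE is a looser bound than a p of 0.05. The comparison lists cover melanocytes and the arrector pili, which may themselves fall with follicles, so these contrasts cannot decide it. Pairs 1 and 5 lean against a lower share of such tissue as the whole cause without excluding it. In pairs 2, 3 and 4 the sebaceous list was lower and the fibroblast list higher. A difference of affected scalp itself stays open, and so does one of tissue handling, since the immediate early list was lowest in pairs 2, 3 and 5, which had the 3 largest fibroblast differences.

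Keratin-associated proteins were lower by a mean of −0.65 log2, in 3 of 5 pairs. They moved in the same direction as the hair shaft keratins in 5 of 5 pairs, and as the inner root sheath list in 4 of 5. Fewer hair follicles in the affected samples could produce the falls of pairs 1, 3 and 4. It would not produce the rises of pairs 2 and 5, at 0.70 and 0.23 for keratin-associated proteins and 0.53 and 0.58 for hair shaft keratins. The agreement therefore shows that these lists move together, and not that follicles were fewer in affected scalp. The outer root sheath and bulge list was lower in all 5 pairs, and so moved with the keratin-associated proteins in only 3 of 5. A difference in follicle number alone stays open. A few transcripts read by the probes of many near-identical family members could also produce the size of the change. The 11 members without a listed sibling were lower in all 3 pairs in which the list was lower, which by the bound first written excludes it, but their mean of −0.0978 lies within its SD of 0.916, and by a bound on the spread added after the value was seen it cannot be told apart from a change of the whole family. Whether follicles were lost to the disease or sampled unevenly was not tested.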

How the results depend on the processing

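The preset correlation of 0.05, the exact exchange and the unadjusted threshold were chosen after the data were seen. Of 27 called lists, 11 were kept under every alternative to the fit, scaling and filter and without each pair, namely fibroblast activation, metalloproteinases, dermal matrix, keratin-associated proteins, outer root sheath and bulge, sebaceous gland, epidermal differentiation, macrophages, mast cells, immediate early genes and complement. None was kept with an estimated correlation, by directional fry or by exact exchange. The exact exchange can call no list with 5 pairs, since its smallest two-sided p is 0.0625, so it says nothing about stability. Mixed fry, which asks for change in either direction, called 5 lists, 3 of them among these 11 (outer root sheath and bulge, mast cells and complement). The cause of the changes below was not tested.

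The count of 27 lists became 16 without the dimmest 50% of probe sets, 14 with a preset correlation of 0.05, 0 with the estimated correlation, 0 by directional fry and 0 by exact exchange, and ranged from 15 (without pair 4) to 28 when 1 pair was left out. With no replicate block it was 19, and 8 lists lost their call. The 33 list members past the threshold over the list alone became 3 with no replicate block, 8 with patient as a random block and 77 with an intensity trend, and ranged from 19 (without pair 3) through 21 (without pair 4) to 51 (without pair 5). The block changed no count of single genes. Genes past the threshold rose from 0 to 2 with an intensity trend, both lower (lowest adjusted p = 0.0130), and 1266 (608 higher, 658 lower) had an unadjusted p under 0.05.

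The growth factor list lost its call at 0.0695 with quantile normalization, 0.0557 with array weights, and 0.0682 with a preset correlation of 0.05 or an estimated one, and ranged from 0.0347 to 0.105 without 1 pair. The fibroblast list, at 0.340, and the metalloproteinase list, at 0.342, lost theirs with an estimated correlation, by directional fry and by exact exchange. Direction turned for chemokines without the dimmest 50% (−0.0199). Without 1 pair, the range was −0.0684 to 0.106 for dendritic cells, −0.485 to 0.411 for red blood cells, −0.386 to 0.0106 for hair shaft keratins and −0.297 to 0.0194 for eccrine and apocrine glands. Of 2529 values of 187 named genes under alternatives, 9 changed direction. Signal over background limits the dim genes, HRNR, MMP13, CXCL13 and DEFB4A in control scalp among them.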

Other observations

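The test in this part was chosen after the result was seen. Among the largest log2 differences were genes outside the naming rule, chosen after their values were seen. TCN1, a vitamin B12 binding protein of secretions, was higher in affected scalp by 1.21 ± 0.29 log2 (SE, n = 5 pairs), in 4 of 5 pairs. ACSM6, of the acyl-CoA synthetases, and FAR2, which makes wax alcohols, differed by −1.03 ± 0.23 and −1.01 ± 0.41, and FAR2 was at −0.67 without pair 3. PIP, a secretory protein of apocrine glands, differed by −1.07 ± 0.53, or −0.32 without pair 5. None of these passed the threshold over all genes.

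ZIC1, a transcription factor whose level differs between skin regions, was higher in affected scalp in 5 of 5 pairs. As a hypothesis, affected and control samples may come from different scalp areas. Of 50 other positional regulators 40 were measured, and 4 had an unadjusted p under 0.05. PRRX1 and DLX5 were higher by 0.51 and 0.39 log2, and HOXC10 and MEIS2 were at −0.43 and −0.25. Their mean absolute moderated statistic lay at percentile 93.7 of 10000 random lists matched on mean signal. The percentile lay between the bounds set for and against it, so a difference in scalp area cannot be told apart from chance here.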
